A study of Mus musculus with 5 samples.

How the data were processed

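The series holds 10x Genomics 3' single-cell RNA libraries, kit version 3.1, of dissected mouse limbus and adjoining tissue, with 1 library for each of 5 groups: uninjured, and days 2, 5, 10 and 40 after injury. Per the labels' protocols, tissue was digested for 1 hour in collagenase A (2 mg/ml) and, at 37 °C, for another hour in trypsin, then passed through a 40 µm strainer, and loaded at about 10000 cells per library. All libraries belong to batch 1, per the labels. The reads were counted with Cell Ranger 4.0.0 against mm10 (GRCm38), per the submitters' processing notes. The deposited matrices hold the raw count of UMIs per gene and barcode, per the file headers and the whole-number values, with 32285 genes and 6794880 barcodes each and with no filter on barcodes. No cell annotation was used here. The number of mice in each library and their sex are not given in the sources used here. Green fluorescent protein is not among the listed features. Genes are named by the symbols that the files pair with Ensembl identifiers.

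All further values were computed from these counts with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. The cell filter, the cell class markers, the gene lists, the rule for named genes, the comparisons and a set of alternatives were chosen before the data were examined; those added later are named as such in the closing section. A barcode was kept with at least 1000 UMIs, 400 genes and at most 20% mitochondrial UMIs, which left 6655, 6956, 7068, 5180 and 4927 barcodes before the mitochondrial limit removed 195, 66, 114, 107 and 192 (uninjured, days 2, 5, 10 and 40). Barcodes of 1000 or more UMIs held 72.3, 76.3, 73.7, 70.0 and 65.1% of the UMIs of each library. Scrublet, with an expected rate of 6%, called 0, 150, 0, 3 and 25 doublets, which were removed. In the uninjured, day 5 and day 10 libraries it called fewer than 0.5% of cells, so the caller has not worked there and doublets remain. Epithelial clusters 0, 10, 14, 19 and 23 have a median UMI count 1.51 to 2.36 times that of their library and may hold doublets. Removing the top 5% of doublet scores in every library was added as an alternative.

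Kept cells of all libraries were clustered together without batch integration, on the log of counts per 10000, 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 1, which gave 27 clusters. Classes were named from fixed markers. A cluster took a class other than epithelium when its score for that class, the mean log2 ratio of its marker CPM to the mean over clusters, reached 1.5 and at least 3 markers were found in 10% of its cells. The others were called epithelial-like when at least 6 epithelial markers were found in 10% of cells, which gave 17 clusters. The stromal-like clusters 12, 16 and 18 were led by Col3a1, Kera and Saa3, the macrophage-like cluster 21 by Lyz2 and Cd74, the neutrophil-like one by S100a8, the mural-like one by Rgs5, the endothelial-like one by Pecam1 and the T or NK-like one by Ccl5 and Cd3g. The macrophage-like cluster has 3 macrophage and 3 dendritic markers among its leading genes. Cluster 1, with 1939 cells, a median of 1691 UMIs and 10.7% mitochondrial UMIs, stayed unnamed because its median was under 1/3 of that of its libraries and none of its leading genes was an epithelial marker. The numeric limits of the naming rule were set after the data had been examined. Shares carry exact Clopper-Pearson binomial intervals.

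UMIs were summed over a class in each library and expressed as CPM. Summed epithelial UMIs were 39296417, 39269545, 36919513, 30267568 and 29951236, and summed stromal UMIs 3668396, 3917858, 3195078, 3067773 and 2631742. Each injured library was compared with the uninjured one by the ratio of CPM, with the exact conditional binomial 95% interval of a ratio of Poisson counts, for genes with at least 20 UMIs in both libraries together; a library at 0 was set at 3 counts. Genes mostly expressed in another cell type reach a class through free RNA, whose share was estimated from near-empty barcodes of 10 to 100 UMIs, with stromal genes for epithelium and keratins for stroma. No free RNA was subtracted in the values reported first. Named genes are the members of the fixed lists, and, per comparison, the 10 highest and 10 lowest ratios in epithelium and the 6 highest and 6 lowest in stroma. These had at least 100 UMIs, 50 CPM in the higher library and an interval that excludes 1, and left out mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed genes and genes below 0.2 times their CPM in another class of 50 or more cells, both in the library where the gene was higher. Smaller classes were not compared, among them the macrophage-like (37) and neutrophil-like (6) cells of the uninjured library, the neutrophil-like cells at day 2 (46) and the mural-like cells at day 5 (24). A gene that this rule also takes is not reported here. In each list, members at 1.5-fold or more were counted, and the median log2 ratio was placed among the medians of 10000 random lists of equal size matched on mean expression in 20 bins. This percentile describes these libraries and is no test.

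The lists covered limbal or basal progenitors, active inner limbus, corneal differentiation, conjunctiva, goblet secretion, skin-type cornification, wound keratins and alarmins, wound matrix and migration, EGFR ligands and growth factors, proliferation, immediate early genes, heat shock, interferon-stimulated genes, antigen presentation, cytokines and chemokines, pluripotency factors, mesenchymal transition, cell cycle inhibitors and senescence, the Notch, Wnt, and BMP and TGF-beta pathways, glycolysis, oxidative phosphorylation, keratocytes, activated fibroblasts and matrix, stromal niche signals, 2 macrophage lists, sex-linked genes and 2 checks for free RNA. Mx1, Aldoa, Ccl21a and Zp4-ps are not in the files under these names. Cells were thinned to 1000 UMIs before shares of cells with a UMI of a gene were compared, and no cell was left out by this. Cells with at least 2 Xist UMIs and no Y-linked UMI, or with Y-linked UMIs and no Xist UMI, were taken as Xist or Y-linked cells. Macrophage-like ratios were not computed, because the uninjured library has 37 such cells, below the minimum of 50.

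The ratio step was tested on simulated Poisson counts drawn from the real means of each comparison, with 200 genes changed. Such draws hold no variation between cells or animals, so the rates below cover counting error only. In epithelium, over 13627 to 13873 genes, the interval held the true ratio for 95.3 to 95.7% of genes and excluded 1 for 94.9 to 98.5% of genes changed by 1.5-fold and for 100% of those changed by 2-fold or 4-fold. In stroma, over 11430 to 11742 genes, these were 95.9 to 96.3%, 81.4 to 89.8%, 97.1 to 100% and 100%. Of genes simulated without change, 0.791 to 0.849% in epithelium and 1.76 to 1.97% in stroma passed 1.5-fold with an interval that excludes 1. Of 100 unchanged lists per comparison, 2 to 6% in epithelium and 2 to 7% in stroma fell outside the percentiles 2.5 to 97.5. Alternatives varied the cell filter, doublet removal, clustering, thinning depth, free RNA, scaling, weighting of cells and the epithelial clusters used. After the mixed sex of the uninjured library had been seen, the comparisons were repeated with uninjured cells of the matching sex.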

Results

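Single-cell RNA was measured in limbal tissue of mice that carry green fluorescent protein under the Krt15 promoter. The limbus is the rim between cornea and conjunctiva where corneal epithelial stem cells reside. There were 5 libraries, 1 per group: uninjured eyes, and days 2, 5, 10 and 40 after the limbal epithelium, the marginal conjunctiva and the peripheral cornea had been removed with a rotating brush. Each library was made from epithelium and stroma dissected together with about 0.5 mm of adjoining tissue. Total UMIs (counted RNA molecules) were 62904153 in the uninjured library, 62140099 at day 2, 57150272 at day 5, 50574219 at day 10 and 53917530 at day 40. After filtering, 6460, 6740, 6954, 5070 and 4710 cells were kept in the same order, with median UMIs per cell of 5522, 5657.5, 4647.5, 5264.5 and 4907. With 1 library per group, no difference between groups has a replicate check, and no test was made. Intervals are 95% and cover counting error only. All 4 comparisons use the same uninjured library, so its own deviations enter each of them.

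Epithelial-like cells were the main class in every library, at 74.3% of kept cells in the uninjured library (73.2 to 75.3%), 75.7% at day 2, 80.3% at day 5, 74.6% at day 10 and 71.0% at day 40. Stromal-like cells, the fibroblasts and keratocytes that make the collagen of the cornea, were 12.2, 12.6, 10.3, 12.9 and 14.2% in the same order. Macrophage-like cells were 0.573% of the uninjured cells (0.404 to 0.789%) and 6.90% at day 2 (6.31 to 7.53%), then 2.69, 1.78 and 1.64% at days 5, 10 and 40. Neutrophil-like cells were 0.093, 0.682, 0.043, 0.099 and 0.382% in library order (6, 46, 3, 5 and 18 cells). T or NK-like cells were 1.99% at day 10 (1.63 to 2.42%) against 0.341% in the uninjured library, 0.0890% at day 2, 0.388% at day 5 and 0.382% at day 40. Mural-like cells, which wrap small vessels, were 0.774, 0.252, 0.345, 0.375 and 1.59%, and blood endothelial-like cells 1.01, 0.579, 0.777, 0.710 and 1.51%. All immune-like classes together held 1.01, 7.67, 3.12, 3.87 and 2.40% of cells. Unnamed cells of low UMI count made up 10.2, 2.61, 4.82, 7.24 and 8.51%, which lowers the share of every other class to a different degree in each library. In this unnamed cluster 10 epithelial markers were found in at least 10% of cells. Of named cells alone, the epithelial-like share was 82.7, 77.7, 84.4, 80.4 and 77.6%, so the order of the uninjured and day 2 libraries turns. Tissue was dissociated as a whole and about 10000 cells were loaded per library, so the shares are of captured cells.

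**Figure D1:**
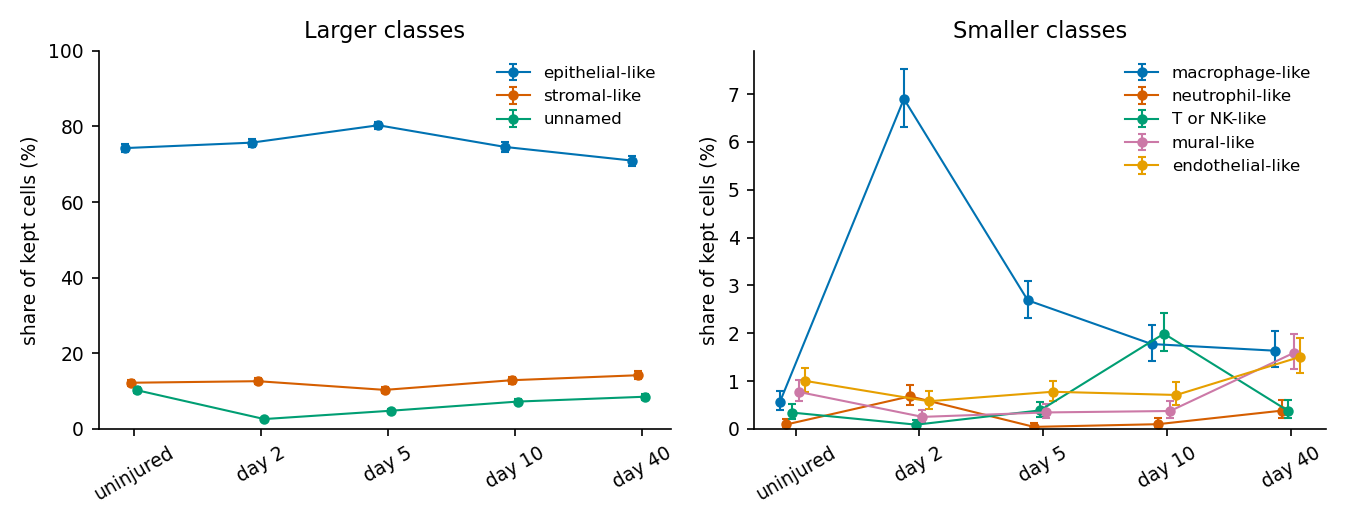
Share of kept cells (%) in each class, by library; points are single libraries and bars are exact binomial 95% intervals for counting error. Macrophage-like cells were 6.90% at day 2 and 0.573% in the uninjured library.

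RNA of both sexes was present in the uninjured library, whereas each injured library held RNA of 1 sex. Xist, the RNA that coats the inactive X chromosome of female cells, was at 1030 CPM (UMIs per 1000000 of the class and library) in uninjured epithelial-like cells and 1309 at day 10, and at 0.05, 0.03 and 0 at days 2, 5 and 40. The summed Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at 29.4 CPM in the uninjured library, 111, 123 and 125 at days 2, 5 and 40, and 0 at day 10. In the uninjured library, 3195 epithelial-like cells had Xist alone and 571 had Y-linked RNA alone. Within this library, Xist cells had lower interferon-stimulated genes than Y-linked cells (median log2 ratio -1.96) and lower antigen presentation genes (-0.60), and higher wound keratin and alarmin genes (0.89) and cornification genes (0.62). Values against uninjured cells of the matching sex (571 epithelial-like and 74 stromal-like Y-linked cells, or Xist cells for day 10) are given below where they turn a direction or move a named ratio by over 1.5 times. With 74 stromal-like cells, several of these rest on 0 to 3 UMIs and carry wide intervals. The stromal-like Y-linked cells also hold less epithelial RNA. Krt15 was at 156 CPM in them and 2754 in uninjured stromal-like Xist cells, and Krt12 at 2504 and 6155. In epithelial-like cells Krt15 was at 7896 and 8212 CPM. Turns of epithelial genes in stroma on this baseline therefore cannot be assigned to sex.

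**Figure D2:**
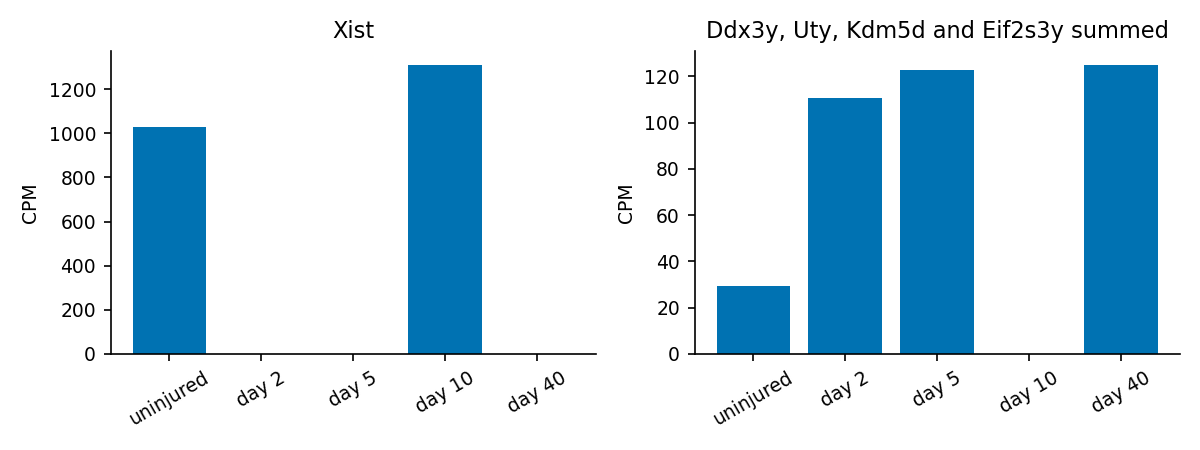
CPM of Xist (left) and of the summed Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y (right) in epithelial-like cells, 1 bar per library. The uninjured library holds both, with Xist at 1030 and Y-linked RNA at 29.4 CPM.

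The day 2 comparison asks which epithelial genes differ early after the injury. Krt15, a keratin used as a marker of limbal basal cells, was 4.09-fold lower at day 2 than in uninjured epithelium (interval 4.06 to 4.12), and Gpha2, a hormone subunit used as a marker of quiescent limbal stem cells, was 3.38-fold lower (3.25 to 3.53). Krt14, a keratin of basal cells, was 2.54-fold higher (2.52 to 2.57), and Itgb4, which anchors basal cells to the basement membrane, was 2.10-fold higher. Krt4, a conjunctival keratin, was 19.4-fold lower (18.4 to 20.5), while Krt12, the keratin of differentiated cornea, was 1.16-fold higher. With epithelial-like cells of all libraries clustered alone, Krt15 was highest in sub-clusters 14 and 0 (23810.5 and 18526 CPM), as was Krt4 (3180 and 1261). Sub-clusters 2 and 13, with the highest Gpha2, had Krt15 at 1702 and 3335 CPM. They held 5.77 and 5.09% of uninjured epithelium (277 and 244 cells) and 0.216 and 1.37% at day 2 (11 and 70 cells). Sub-clusters 14 and 0 held 5.13 and 7.78% of uninjured epithelium and 0.451% each at day 2. The lower Krt15 thus does not by itself mark a loss of limbal basal cells. The DNA replication genes Mcm5 and Rrm2, members of the proliferation list, were 2.68 and 2.58-fold higher.

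Of the 18 measured limbal or basal progenitor genes, 4 were 1.5-fold or more higher at day 2 and 8 were 1.5-fold or more lower, with a median log2 ratio of -0.24. The lower members included Cebpd (log2 ratio -2.07), a regulator of limbal quiescence, and Txnip (-1.60), and the higher ones included Ifitm3 (1.26). Of 7 active inner-limbal genes, 4 were higher and none lower (median 0.79, percentile 99.98 among 10000 random lists matched on expression), with the metallothioneins Mt1 and Mt2 at 1.38 and 1.01. Among 22 proliferation genes, 16 were higher and none lower (median 0.70), although Mki67 itself was at 0.13 (-0.12 with the mean over cells). Conjunctival genes were mostly lower, 9 of 13 with 1 higher (median -0.98), with the mucin Muc4 at -1.28 and Psca at -1.49. Of 18 corneal differentiation genes, 2 were higher and 4 lower (median -0.23). Of 13 glycolysis genes, 6 were higher, with Gapdh at 1.07 and Eno1 at 1.35 (median 0.45), and 4 of 11 heat shock genes were higher, with Hspa8 at 1.06 (median 0.49). Cornification genes were lower in 6 of 11 and higher in 1 (median -0.73), and cytokine and chemokine genes lower in 10 of 18 and higher in 4 (median -0.76). Wound keratin and alarmin genes were lower in 6 of 14 and higher in 2 (median -0.34), with the wound keratin Krt16 at 1.37. Of 19 wound matrix and migration genes 6 were higher and 1 lower (median 0.22, or -0.06 with the mean over cells), and the integrin Itga3 was at 1.08. With uninjured Y-linked cells as the baseline, the cytokine and chemokine median turned to 0.31 and the wound keratin and alarmin median to 0.34, and Psca was at -0.90.

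The highest day 2 ratios in epithelial-like cells began with Fscn1, an actin bundler of migrating cells, at 14.0-fold (11.9 to 16.5). The replication-dependent histones Hist1h2ap (8.99-fold) and Hist1h2ae (6.66-fold) and the matrix protein gene Ecm1 (8.47-fold) came next. Pthlh was at 3.84-fold, the actin-binding gene Tmsb10 at 3.76-fold, Clu at 3.69-fold, Lxn at 3.37-fold and the clock output gene Dbp at 3.23-fold. The lowest were the protease inhibitor Serpinb3a, 20.2-fold lower (18.1 to 22.6), then Krt4, the lipid carrier Apoe at 11.9-fold (564 CPM in uninjured epithelium and 10768 in the 37 uninjured macrophage-like cells), S100a9, an alarmin that neutrophils express too, at 11.7-fold, Lgi2 at 10.1-fold, Wfdc18 at 8.39-fold, Ifit1bl1 at 5.44-fold, the transporter Slc5a8 at 5.34-fold, the interferon-stimulated Ifi27l2a at 4.67-fold and the glutathione transferase Gstm1 at 4.40-fold. Against uninjured cells with Y-linked RNA alone, Wfdc18 turned to higher (log2 ratio 1.81), and the log2 ratios of S100a9, Fscn1, Dbp, Pthlh, Serpinb3a and Ifi27l2a were -1.82, 3.13, 0.69, 2.92, -3.63 and -3.81. The mesenchymal genes Vim (log2 ratio 2.28) and Sparc (2.60) were also higher at day 2. The estimated share of free RNA in this class, a ratio to near-empty barcodes, was 6.97% there and 3.27% in the uninjured library. Near-empty barcodes had Kera, Dcn and Col1a1 at 36.2 (5 UMIs), 318 and 123 CPM at day 2, against 93.1, 733.5 and 241. Epithelium had them at 3.6, 32.3 and 8.3 CPM against 3.7, 25.8 and 7.4. The higher share thus went mainly with lower near-empty levels. Saa3, high in day 2 stroma, was at 13.6 CPM in day 2 epithelium against 0.5. Of the 7 mesenchymal transition genes measured, 4 were higher and none lower (median 0.70). With finer clustering (resolution 2) the median turned to -0.58, with Vim at 0.60 and Sparc at 1.14.

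Shares of cells were compared after each cell had been thinned to 1000 UMIs. A UMI of Krt15 was found in 66.4% of uninjured epithelial-like cells and 30.7% at day 2, then in 61.1, 59.3 and 60.5% at days 5, 10 and 40. For Krt14 the shares were 53.4, 84.0, 47.3, 48.6 and 51.3%, and for Krt12 they were 94.6, 99.2, 97.3, 96.5 and 93.0%. Krt4 was found in 13.2, 1.20, 11.8, 11 and 9.79%. A UMI of Mki67 or Top2a, genes of dividing cells, was found in 13.5, 18.7, 11, 11.5 and 11.1%. Krt12 and Krt15 were found together in 61.5% of uninjured cells and 29.9% at day 2, where the products of both shares are 62.8 and 30.4%. With Krt12 in 94.6 and 99.2% of these cells, the joint share has to lie near the product. It therefore cannot show whether the 2 genes go together.

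Stromal-like cells, which give a background level for the keratins, had a UMI of Krt15 in 29.3, 11, 21.3, 17.6 and 20.8% of cells, of Krt14 in 22.9, 28.6, 12.7, 14.5 and 12.7%, of Krt12 in 78.3, 75.1, 66.0, 67.5 and 74.1%, of Krt4 in 3.80, 0.235, 5.15, 1.38 and 1.64%, and of Mki67 or Top2a, which dividing stromal cells express themselves, in 2.54, 3.88, 4.18, 2.76 and 1.79%. Gpha2 was found in 15.8, 6.43, 15.3, 15.8 and 21.5% of epithelial-like cells and in 26.1, 47.6, 16.3, 17.3 and 22.3% of stromal-like cells, so the stromal share cannot serve as its background; in blood endothelial-like cells it was 4.62, 0, 7.41, 8.33 and 2.82%. The share of 0 rests on 39 cells. Before thinning, epithelial-like cells had median UMIs of 7048, 6641, 5152, 6432.5 and 6668.5, stromal-like cells 3910, 3689, 3765.5, 4020 and 3477, and blood endothelial-like cells 2396, 3216, 2374.5, 2150.5 and 2366. Unthinned, the epithelial shares were 89.0, 57.2, 82.3, 81.0 and 85.6% for Krt15, 79.3, 96.4, 69.6, 73.2 and 76.0% for Krt14, 99.8, 100.0, 99.8, 99.8 and 99.8% for Krt12, 36.8, 23.5, 30.6, 33.4 and 46.1% for Gpha2, 29.0, 3.51, 24, 23.6 and 22.3% for Krt4, and 25, 39.8, 20.2, 22.8 and 21.5% for Mki67 or Top2a.

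**Figure D3:**
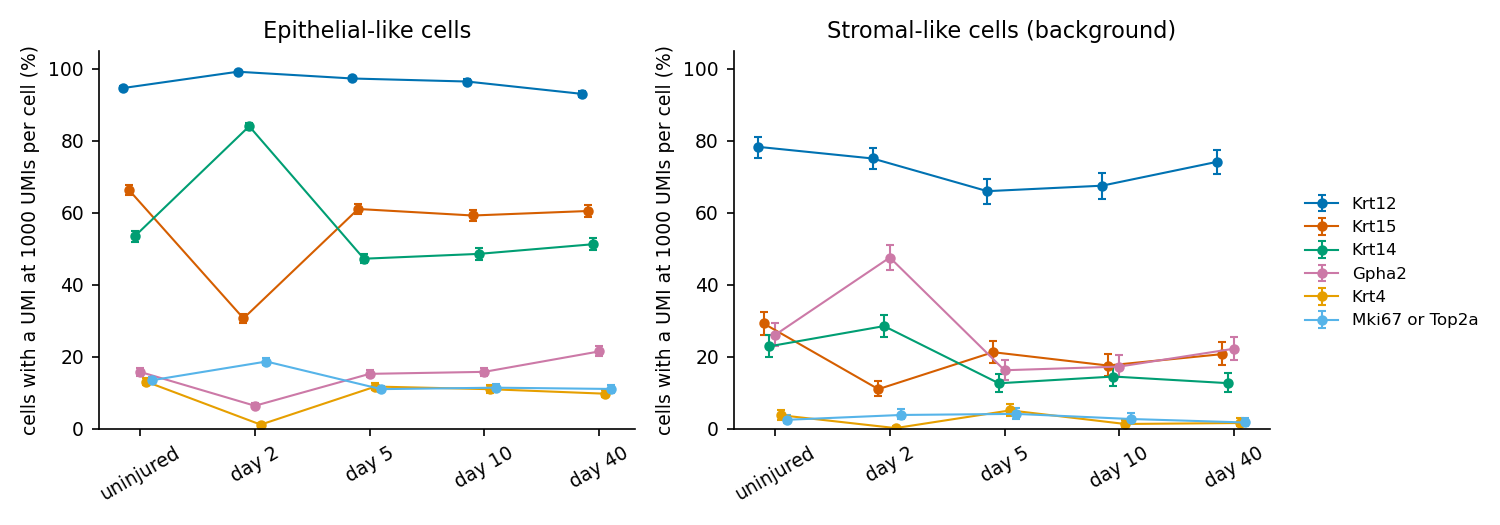
Share of cells (%) with a UMI of each gene after thinning to 1000 UMIs per cell, in epithelial-like (left) and stromal-like cells (right), by library; bars are exact binomial 95% intervals for counting error. In epithelium, Krt15 was found in 66.4% of uninjured cells and 30.7% at day 2, and Krt14 in 53.4 and 84.0%.

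Most day 2 epithelium lay in clusters of its own: clusters 6 and 17 held 1642 and 1145 of its 5102 cells, and 92.6 and 98.9% of these clusters came from this library. A cluster that comes mostly from 1 library may mark the library rather than a cell type.

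In day 2 stroma, the acute-phase gene Saa3 was at 8726 CPM against 1 UMI in the uninjured library (ratio 32011, interval 5745 to 1264409). Timp1, an inhibitor of matrix proteases, was 110-fold higher (64.0 to 206), the macrophage gene Mpeg1 119-fold, the iron-binding alarmin Lcn2 62.9-fold and the protease inhibitor Slpi 23.3-fold, and Saa1 was at a ratio of 199 over 1 UMI (35.2 to 7877). S100a4, a calcium-binding gene of migrating fibroblasts, was 11.5-fold higher, the chemokines Ccl2, Ccl7 and Cxcl2 were 4.22, 6.29 and 11.8-fold higher, and the intermediate filament gene Vim 3.32-fold. Slpi and Cxcl2 are also among the leading genes of the neutrophil-like cluster. The Mpeg1 ratio rests on 4 UMIs in the uninjured library (interval 46.3 to 440). At day 2 Mpeg1 was at 130 CPM in stroma and 648 in another class, so it passed the rule for free RNA only narrowly. The collagen-binding proteoglycan genes Kera, a keratocyte gene that leads cluster 16, and Fmod, a leading gene of cluster 12, were 1.94 and 2.09-fold lower. Dividing-cell genes were higher, with 19 of 22 proliferation genes at 1.5-fold or more (median log2 ratio 1.23) and the cyclin Ccnb2 4.62-fold higher. On the Y-linked baseline, Ccl2 and Ccl7 were at log2 ratios of 0.80 (0.46 to 1.16) and 1.16 (0.48 to 1.93). There Cxcl2 (2 UMIs) was at 4.95 (3.09 to 8.0), Slpi and Mpeg1 (1 UMI each) at 5.22 (2.73 to 10.53) and 5.67 (3.19 to 10.98), and Timp1 (3 UMIs) at 5.66 (4.11 to 7.94). Saa3 and Saa1 had no UMI in those 74 cells and were at least 1137-fold and 7.05-fold higher, against a floor of 3 UMIs.

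Of 25 measured stromal niche signal genes, 13 were lower at day 2 and 2 higher (median log2 ratio -0.61), with the Wnt inhibitor Sfrp1 3.66-fold lower and the stem cell chemokine Cxcl12 3.35-fold lower. The Wnt ligand Wnt2 (2 UMIs, 16.0-fold lower, 4.07 to 138) and the Wnt enhancer Rspo1 (3 UMIs, 10.3-fold lower, 3.20 to 53.0) rest on few counts, and Wnt2 had no UMI in uninjured Y-linked cells, which leaves no ratio on that baseline. Of 22 activated fibroblast and matrix genes, 8 were higher and 3 lower (median 0.28, or -0.06 with the UMI minimum set per library), with the glycoprotein Tnc 3.88-fold higher, and Cthrc1 at a log2 ratio of -1.77. Of 12 keratocyte genes 3 were lower and none higher (median -0.25). Against the 74 uninjured cells with Y-linked RNA alone, the niche median turned to 0.06, Sfrp1 was at -0.94 (-1.81 to 0.04) and Tnc at 3.18 (2.04 to 4.63). On the same baseline Cxcl12 turned to 1.89 (1 UMI, -0.68 to 7.23), Igf1 from -1.22 to 1.00 (2 UMIs, -0.95 to 4.09) and Rspo1 was at -1.74 (1 UMI, -5.38 to 3.97), intervals that include both directions.

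The lowest stromal ratios at day 2 were those of Cmah (11.6-fold), Krt17 (11.2-fold), Krt15 (9.52-fold), Akr1b7 (9.19-fold), Cbr2 (8.87-fold) and Sprr1a (7.51-fold). All 6 were higher in uninjured epithelial-like cells (264, 255, 7911, 227, 486 and 349 CPM) than in uninjured stroma (62.2, 63, 1975, 58.6, 118 and 138), and the estimated free RNA share of stromal-like cells was 25.8% in the uninjured library and 15.3, 13.0, 15.5 and 10.6% at days 2, 5, 10 and 40. The ratio of Krt15 turned to higher against uninjured Y-linked cells (log2 ratio 0.41, 0.04 to 0.81), a baseline with less epithelial RNA than the uninjured Xist cells of this class. Akr1b7 (2 UMIs there) and Cmah (1 UMI) were then at 0.32 (-1.69 to 3.44) and 1.07 (-1.57 to 6.44), Krt17 at -0.87 (-2.42 to 1.13), Sprr1a at -1.16 (-1.95 to -0.27) and Cbr2 at -1.33 (-2.22 to -0.32). Akr1b7 also turned with at most 10% mitochondrial UMIs (0.60) and at resolution 2 (0.27). Cluster 18 held 81.8% of day 2 stroma and cluster 16 held 81.6% of uninjured stroma, so these ratios also compare different clusters.

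**Figure D4:**
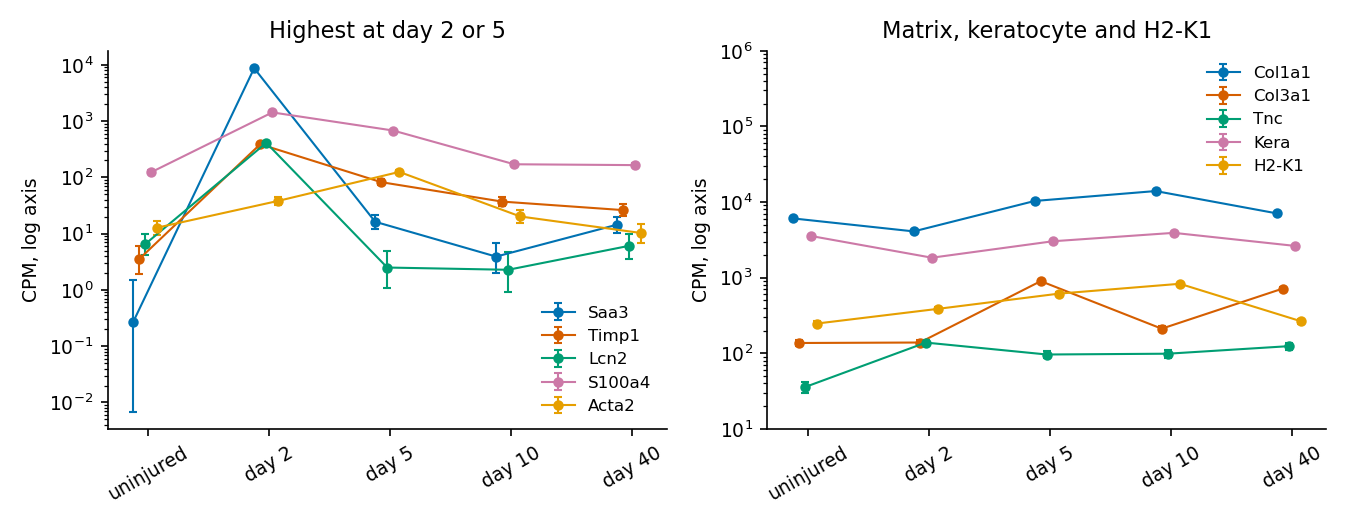
CPM (log axis) of named genes in stromal-like cells, by library; bars are exact Poisson 95% intervals for counting error. Saa3 was at 8726 CPM at day 2, and Acta2 was highest of the 5 libraries at day 5.

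By day 5 the question is which genes return and which stay apart from the uninjured library. Krt15 and Gpha2 were both at 1.04-fold lower in epithelial-like cells (log2 ratios 0.04 and 0.04 with libraries scaled by the median gene ratio), and Krt14 was 1.38-fold lower. Krt17, a keratin of limbal and wounded epithelium, was 4.37-fold lower, and S100a9 (7.99-fold) and Serpinb3a (5.85-fold) were lower as well. Interferon-stimulated genes were higher in 10 of 17 and lower in 1 (median log2 ratio 0.82), with Ifit3 at 1.22 and Irf7, a regulator of the interferon response, at 1.03, and antigen presentation genes in 5 of 11 (median 0.47), with B2m at 0.75. Against uninjured cells with Y-linked RNA the interferon median turned to -0.20, Ifit3 to -0.02, Irf7 to -0.04 and B2m to -0.57, and the antigen presentation median was 0.07.

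Among the highest epithelial ratios at day 5, the alcohol dehydrogenase gene Adh6a was at 3.47-fold, Hist1h2ap at 2.95-fold, AA467197 at 2.92-fold, the cornified envelope gene Lce3a at 2.45-fold, the stress gene Chac1 at 2.40-fold, Ifit1bl1 at 2.27-fold, Mab21l4 at 2.15-fold, the protease Prss22 at 2.13-fold and Ly6a at 2.11-fold. The lowest also included Wfdc18 (3.86-fold), the growth factor Ptn (2.80-fold), Apoe (2.02-fold), Spink5 (1.99-fold), the taurine transporter Slc6a6 (1.84-fold), the mechanosensitive channel Piezo2 (1.82-fold) and Tmem176b (1.71-fold). Wfdc18 turned to a log2 ratio of 2.93 against uninjured Y-linked cells, S100a9 was at -1.27, Krt17 at -1.20 and Serpinb3a at -1.84, and the higher genes AA467197 and Chac1 were at 2.17 and 2.24. Lce3a was at 5.90 on this baseline (4.85 to 7.21, 7 UMIs in those cells). Limbal or basal progenitor genes had a median of -0.33 (4 of 18 lower, none higher), proliferation genes -0.31 (1 of 22 lower), wound keratin and alarmin genes -0.52 (6 of 14 lower; 0.27 against uninjured Y-linked cells) and Wnt pathway genes -0.58 (3 of 6 lower). Conjunctival genes had a median of 0.38 (3 of 13 higher, 1 lower), with Psca at 0.87 (1.46 on the Y-linked baseline) and the mucin Muc20 at 0.73, and corneal differentiation genes 0.06 (1 of 18 higher).

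In day 5 stroma, genes of activated fibroblasts were higher in 15 of 22 and lower in 1 (median log2 ratio 0.84). The smooth muscle actin gene Acta2 was 9.77-fold higher (7.21 to 13.5), Tagln 5.08-fold, the scar-type collagen Col3a1 6.57-fold, Timp1 23.2-fold and fibronectin, Fn1, 2.89-fold. The other highest ratios were those of Dclk1 (7.97-fold), the lubricin gene Prg4 (6.26-fold) and the small proteoglycan Aspn (5.61-fold). Proliferation genes were higher in 11 of 22 (median 0.60), and the cyclin Ccnb2 was at 4.45-fold. Tagln turned to a log2 ratio of -0.52, and Acta2 moved to 1.21, when the UMI minimum was set per library. Both are also leading genes of the mural-like cluster, and their source was not tested; Rgs5, the first gene of that cluster, was at a log2 ratio of -0.74 in stromal-like cells (13 UMIs at day 5 and 25 in the uninjured library). The lowest were S100a9 (34.3-fold), Krt17 (13.4-fold), Myoc (7.15-fold), Sprr1a (6.30-fold), the neutrophil chemokine Cxcl5 (5.59-fold) and Spink5 (4.29-fold). Niche signals were lower in 8 of 28 and higher in 3 (median -0.29), and the median turned to 0.24 against the 74 uninjured Y-linked cells; the keratocyte median was -0.01 (2 of 14 higher, 2 lower). Of the lowest genes, Spink5 turned to 1.33 on that baseline (2 UMIs, -0.62 to 4.42), and S100a9 (2 UMIs, -4.32 to 1.68), Krt17 (-2.77 to 0.93), Cxcl5 (-1.26 to 0.33) and Myoc (-1.56 to 0.30) were at -1.71, -1.12, -0.50 and -0.69 with intervals that include 0, and Sprr1a at -0.90 (-1.70 to -0.02). Of the higher genes there, Acta2 was at 5.61 (1 UMI, 3.13 to 10.92), Tagln at 3.82 (1 UMI, 1.31 to 9.13), Dclk1 at 3.88 (3 UMIs, 2.32 to 6.17), Timp1 at 3.42 (3 UMIs, 1.86 to 5.71), Col3a1 at 4.21 and Prg4 at 1.88.

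At day 10, interferon-stimulated and antigen presentation genes were higher in epithelial-like cells, in the library that holds Xist and no Y-linked RNA. In the same cells the check with retinal, lens and blood genes was higher too (5 of 7, median log2 ratio 3.11), with haemoglobin genes at 20.9 CPM against 0.31 in the uninjured library. Of 17 interferon-stimulated genes 14 were 1.5-fold or more higher and none lower (median log2 ratio 1.44, percentile 100 among 10000 random lists). Ifi27l2a was 5.07-fold higher (4.87 to 5.28), and the antiviral genes Ifit3, Ifit1 and Isg15 were 4.07, 3.23 and 3.08-fold higher. B2m, the shared chain of MHC class I, was 3.66-fold higher (3.55 to 3.77), and 10 of 11 antigen presentation genes were higher (median 1.25), among them H2-K1 (log2 ratio 1.20). Against uninjured cells with Xist the interferon median was 2.40, with Ifi27l2a at 4.42, B2m at 3.02, Ifit3 at 3.30, Ifit1 at 2.90 and Isg15 at 3.11.

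The other epithelial genes with the highest ratios at day 10 were Mndal (3.63-fold), Hist1h2ap (3.07-fold), Lce3a (2.84-fold) and Slfn2 (2.61-fold). The lowest were Serpinb3a (2.14-fold), Krt17 (2.05-fold), Piezo2 (1.98-fold), Slc6a6 (1.85-fold), the Wnt modulator Dkk3 (1.76-fold), Zfp36l2 (1.75-fold), Tns4 (1.75-fold), the clock gene Nr1d1 (1.73-fold), Ptn (1.70-fold) and Tmem176a (1.57-fold). Krt15 was 1.06-fold lower and Krt14 1.18-fold lower, and 16 of 18 limbal or basal progenitor genes were within 1.5-fold and 2 lower (median -0.27). All 18 corneal differentiation genes and all 22 proliferation genes were within 1.5-fold, with medians of 0.05 (-0.008 with the mean over cells) and -0.13. Wnt pathway genes were lower in 3 of 6 (median -0.65). The median log2 ratio of all epithelial genes was -0.11 at day 10, and with libraries scaled by the median gene ratio the proliferation median was -0.02 and Krt15 at 0.03.

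In day 10 stroma, 17 of 22 activated fibroblast and matrix genes were higher and none lower (median log2 ratio 0.89), with collagen Col1a1 2.30-fold higher, the matrix protein gene Sparc 2.11-fold and Fn1 2.39-fold. Antigen presentation genes were higher in 8 of 11 (median 0.91), with H2-K1 3.35-fold and H2-D1 2.99-fold higher, and interferon-stimulated genes in 6 of 16 (median 0.54), with the interferon-induced GTPase Iigp1 6.58-fold higher (4.79 to 9.21). The other highest ratios were those of the fibrillar collagen Col11a1 (3.70-fold), Sox4 (3.26-fold) and Col8a1 (3.17-fold). The lowest were S100a9 (13.7-fold), Cxcl5 (8.48-fold), Krt17 (7.73-fold), Spink5 (5.12-fold), Sprr1a (3.75-fold) and the histone Hist1h1b (3.60-fold), and Spink5 turned to a log2 ratio of 0.16 with the top 5% of doublet scores removed. Iigp1 was at 3.31 and S100a9 at -4.37 against uninjured Xist cells. Of the lowest genes, S100a9, Spink5 and Krt17 were at 81.1, 81.1 and 88.1 CPM in those cells. In uninjured stromal-like Y-linked cells, which hold less epithelial RNA, they were at 5.12, 5.12 and 10.2 on few UMIs. Day 10 stroma had them at 3.91, 10.8 and 8.15. Cxcl5 and Sprr1a were also higher in the Xist cells, and Hist1h1b was not. How much of these low ratios comes from RNA of other cells in the uninjured baseline was not tested. Niche signals were lower in 9 of 26 and higher in 1 (median -0.36), and the proliferation median was -0.25 (3 of 21 higher, 4 lower), or 0.38 with free RNA subtracted.

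**Figure D5:**
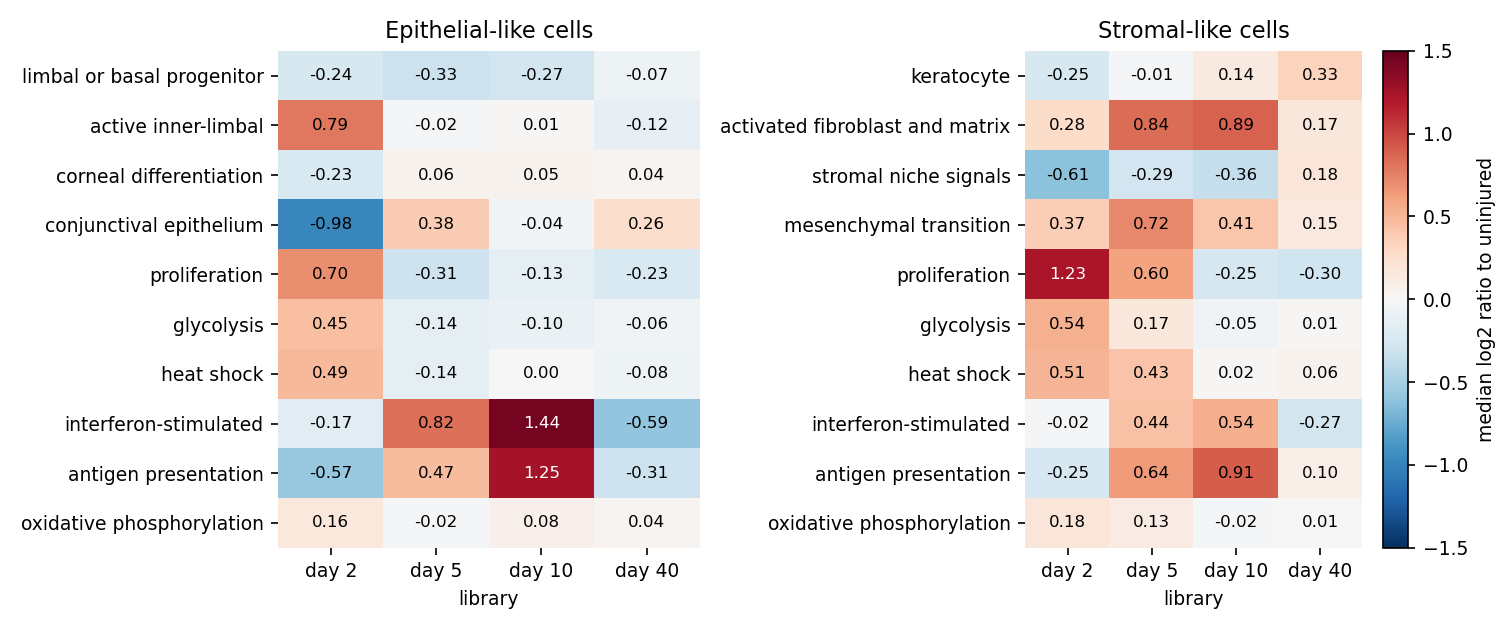
Median log2 ratio to the uninjured library of the measured genes of each list shown, in epithelial-like (left) and stromal-like cells (right), 1 column per library. Epithelial interferon-stimulated genes were at 1.44 at day 10 and -0.59 at day 40; of the medians shown, those that change sign against uninjured cells of the matching sex are, in epithelium, interferon (day 5), glycolysis (days 5 and 40), heat shock (days 5, 10 and 40) and oxidative phosphorylation (day 5), and in stroma niche signals (days 2 and 5), interferon (day 5), mesenchymal transition (days 2 and 40), glycolysis and heat shock (day 40).

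The day 40 comparison asks how near the limbus at that time lies to the uninjured one. In epithelial-like cells the groups that mark limbal and corneal cells had medians near 0: limbal or basal progenitor genes -0.07 (17 of 18 within 1.5-fold), corneal differentiation genes 0.04 (17 of 18 within; -0.10 with the mean over cells) and active inner-limbal genes -0.12 (6 of 7 within). The glycolysis median was -0.06, but 0.12 against uninjured Y-linked cells and 0.02 with the mean over cells. Krt15 was 1.09-fold lower and Gpha2 1.40-fold higher. Farther from 0 were interferon-stimulated genes, lower in 8 of 16 (median -0.59), with Ifi27l2a 7.54-fold lower (6.71 to 8.51), and cornification genes, lower in 3 of 11 (median -0.36), although the cornification median turned to 0.10 against uninjured Y-linked cells. Krt4 was 1.88-fold lower. Proliferation genes had a median of -0.23, with all 22 within 1.5-fold. Conjunctival genes had a median of 0.26, with 10 of 13 within 1.5-fold, Krt4 lower, and Krt8 (log2 ratio 1.39) and Krt18 (0.84, or 1.53 on the Y-linked baseline) higher.

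The highest epithelial ratios at day 40 were those of Hist1h2ap (3.26-fold), Adh6a (2.03-fold), Wdr89 (1.77-fold), Mir205hg (1.73-fold), Pet100 (1.64-fold), Atp5k (1.62-fold), Fam25c (1.61-fold), Ndufa3 (1.56-fold) and Mab21l4 (1.56-fold). Atp5k and Ndufa3 encode parts of the mitochondrial respiratory complexes. Hist1h2ap was higher in all 4 comparisons, at 204, 67.2, 69.9 and 74.1 CPM against 22.8 in the uninjured library. A lasting rise of this gene cannot be told apart from a low level in that 1 shared library. The lowest also included Ifrd1 (1.82-fold), Serpinb3a (1.82-fold), Krt17 (1.70-fold), the vasoactive peptide gene Adm (1.60-fold), Spink5 (1.54-fold), the stress regulator Atf4 (1.51-fold), the gap junction gene Gjb2 (1.51-fold) and Cpeb2 (1.49-fold). Antigen presentation genes had a median of -0.31 (2 of 11 lower), with B2m at -1.23. Against uninjured Y-linked cells the interferon median was -1.61, the antigen presentation median -0.70, Ifi27l2a -4.50, B2m -2.55 and Serpinb3a -0.16, and Krt17 turned to 0.17.

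In day 40 stroma, niche signals were higher in 8 of 26 and lower in 3 (median log2 ratio 0.18). Cxcl12 was 2.85-fold higher (2.27 to 3.59), the growth factor Igf1 2.69-fold, Bmp4 5.19-fold (3.05 to 9.28) and Tgfb3 2.01-fold. The highest ratios were those of the tenascin Tnn (8.26-fold, 5.92 to 11.8), Col3a1 (5.24-fold), Stc1 (3.95-fold), Spp1 (3.88-fold) and Tnc (3.48-fold). The keratocyte median was 0.33 (1 of 12 higher, none lower) and the activated fibroblast median 0.17 (6 of 22 higher, 1 lower; -0.03 with free RNA subtracted), with Postn at 1.56. The lowest ratios were those of epithelial and alarmin genes: Sprr1a (14.5-fold), Spink5 (10.4-fold), S100a9 (8.83-fold), Dsg1a (7.0-fold), Dsc2 (5.68-fold) and Krt19 (5.29-fold). With uninjured Y-linked cells as the baseline, Spink5, S100a9 and Krt19 (2 UMIs each) turned to 0.06 (-2.07 to 3.24), 0.25 (-1.84 to 3.41) and 1.00 (-0.99 to 4.12), and Sprr1a, Dsg1a and Dsc2 were at -2.11, -1.87 and -1.51. S100a9 also turned with the top 5% of doublet scores removed (0.26). Of the higher genes, Cxcl12 was then at 5.14 (1 UMI, 2.65 to 10.45), Igf1 and Spp1 (2 UMIs each) at 3.64 (1.77 to 6.70) and 4.95 (3.08 to 8.0), Col3a1 at 3.88 and Tnc at 3.02, and Stc1, with no UMI in those cells, was at least 14.2-fold higher. Cluster 12 held 45.7% of day 40 stroma while cluster 16 held 81.6% of uninjured stroma.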

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

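The tests of differences between animals and of sex below, and the count of limbal genes against Y-linked cells, were chosen after the results had been seen; those of single clusters, immune RNA and limbal cell loss were written before.

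Interferon-stimulated and antigen presentation genes were higher in day 10 epithelium (medians 1.44 and 1.25). The cells of cluster 15 alone do not account for this: without that cluster, which holds 166 day 10 and 7 uninjured cells and has the highest interferon level, the medians were 1.07 and 1.17. In epithelium clustered alone, sub-cluster 8, led by Ifi27l2a and Ifit3, holds 262 day 10 cells. Some cells of high interferon level may thus remain, and medians without sub-cluster 8 were not computed. RNA from immune cells does not account for the rise either, since the excess would need 20.6% immune RNA where 22 macrophage and T cell markers allow 0.059%, a ratio of 351. A difference between animals stays open, because within the uninjured library Xist cells differed from Y-linked cells by -1.96 in the interferon median, more than day 10 differs from the whole library. Sex and animal cannot be told apart in that contrast, as the number of mice is not given. Xist cells had the lower level in it, whereas the day 10 library, which holds Xist, was at 2.40 against uninjured Xist cells. An effect of the time since injury may equally account for the pattern and was not tested, with 1 library at day 10.

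Krt15, Gpha2 and Krt4 were lower and Krt14 higher in day 2 epithelium (log2 ratios -2.03, -1.76, -4.28 and 1.35). The sex of the animals is argued against, since all 4 genes kept their direction beyond 1.5-fold against uninjured Y-linked cells (-2.03, -1.78, -4.33 and 1.78). Fewer limbal cells among those captured cannot be told apart from lower expression of these genes: of the 30 genes most enriched in the 1062 uninjured cells with at least 2 Gpha2 UMIs, 24, the fewest that the test asked for, were 1.5-fold or more lower at day 2 and 2 higher (median -1.88). Against uninjured Y-linked cells, 20 were lower and 6 higher (median -0.91), which is short of what the test asked for. Sub-clusters 2 and 13, with the highest Gpha2, held 5.77 and 5.09% of uninjured and 0.216 and 1.37% of day 2 epithelium. Since sub-clusters are drawn from expression, these shares cannot separate fewer cells from lower expression. The test covers genes of cells with Gpha2 only, and cannot speak for Krt15 and Krt4. Those were highest in sub-clusters 14 and 0 of epithelium clustered alone. These sub-clusters held 5.13 and 7.78% of uninjured and 0.451% each of day 2 epithelium. Fewer such cells among those captured cannot be told apart from lower expression of Krt15 and Krt4 either, and this was not tested. The higher Krt14 and an effect of the time since injury are left open.

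Y-linked RNA was found at 29.4 CPM in epithelial-like cells of the uninjured library, which also holds Xist at 1030 CPM. In the day 10 library Xist was at 1309 CPM, with no Y-linked UMI. Haemoglobin genes were at 20.9 CPM in day 10 epithelial-like cells, against 0.31, 0.87, 0.3 and 0.17 in the uninjured, day 2, day 5 and day 40 libraries. The epithelial interferon median was 2.03 higher (log2) at day 10 than at day 40, with opposite signs against the uninjured library, a difference that was not tested. The antigen presentation median was 1.82 higher at day 10 than at day 2, and this was not tested either. The proliferation median was 1.01 higher at day 2 than at day 5, an untested difference. The conjunctival median was 1.24 higher at day 40 than at day 2, also untested.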

How the results depend on the processing

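Of the alternatives below, 3 were chosen after the data had been seen: removing the top 5% of doublet scores, using uninjured cells of the matching sex, and adding the unnamed cluster to the epithelium. Among the alternative values of the class shares, the thinned shares and the 9 main list medians, 684 stayed within the interval of the value reported, 174 moved beyond it and 2 reversed (epithelial interferon at day 5 and stromal niche signals at day 2, both with uninjured cells of the matching sex). Among those of other lists and named genes, 7207 stayed, 2036 moved and 82 reversed. For single genes, a reversal was counted only for ratios of 1.5-fold or more, a limit set after the alternatives had been seen. Under it 11 of 2142 epithelial and 40 of 1752 stromal values changed sign; among ratios under 1.5-fold, 118 of 2086 and 91 of 708 did. Over 16 alternatives the epithelial interferon median ranged from 1.35 to 2.40 at day 10 and from -1.61 to -0.54 at day 40, antigen presentation at day 10 from 1.19 to 1.49, proliferation at day 2 from 0.61 to 1.30, and the conjunctival median at day 2 from -0.99 to -0.60. Limbal or basal progenitor medians stayed below 0 on all 4 days, between -0.37 and -0.03. Over 13 alternatives the stromal activated fibroblast median ranged from 0.49 to 0.84 at day 5, from 0.74 to 0.93 at day 10, from -0.06 to 0.32 at day 2 and from -0.03 to 0.20 at day 40. Ranges also took in 0 for epithelial interferon at day 5 (-0.20 to 0.92), conjunctival genes at day 10 (-0.07 to 0.12), corneal differentiation at days 10 (-0.008 to 0.16) and 40 (-0.10 to 0.08), keratocyte genes at day 10 (-0.05 to 0.21) and niche signals at days 2 (-0.72 to 0.06) and 5 (-0.39 to 0.24). Values are given in the order uninjured, day 2, day 5, day 10 and day 40 unless days are named. Except where a filter or a clustering changes which cells enter a class by its construction, the cause of a change was not tested. No paired analysis was possible because each group has 1 library and no result comes from a test. Macrophage alternatives were not run, since the uninjured library has fewer than 50 such cells. Matching the sex of the uninjured cells moved 48 of 153 epithelial and 74 of 146 stromal ratios of 1.5-fold or more by over 1.5 times. Depth limits stromal values too: Wnt2 and Rspo1 had 2 and 3 UMIs at day 2.

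Class shares moved with the cell filter and the clustering. With at least 500 UMIs per cell, the epithelial share was 70.3, 71.3, 78.7, 73.0 and 62.1%, the stromal share 9.82, 11.3, 9.28, 11.6 and 12.2%, and the immune share 1.32% (uninjured), 9.28% (day 2) and 4.55% (day 10). With at least 2000 UMIs per cell, the epithelial share was 84.8, 79.0, 86.0, 82.6 and 81.6%, the stromal share 13.4% (uninjured) and 14.1% (day 10), and the immune share 0.675, 6.76, 2.49, 2.49 and 1.14%. With at most 10% mitochondrial UMIs, these were 83.2, 76.9, 84.7, 80.3 and 77.7%, then 13.9% (day 10) and 16.0% (day 40), and 8.60% (day 2) and 1.96% (day 40). With a UMI minimum set per library, they were 85.6, 80.3, 86.9, 83.6 and 84.2%, then 13.1% (uninjured) and 14.0% (day 10), and 0.617, 6.10, 2.14, 2.01 and 0.789%. With called doublets kept, the epithelial share was 74.5% (day 2) and 76.3% (day 10). At Leiden resolution 0.5 it was 84.4, 78.3, 85.1, 81.7 and 79.5%. At resolution 2 it was 80.4, 77.1, 82.6, 78.6 and 75.4%, with a stromal share of 10.5% (uninjured) and 9.48% (day 5). With the top 5% of doublet scores removed it was 78.2, 77.4, 82.3, 77.9 and 74.8%, with a stromal share of 10.7% (uninjured) and 9.59% (day 5) and an immune share of 1.5% (day 40).

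Shares of epithelial-like cells with a UMI moved with the thinning depth. At 500 UMIs they were 8.80, 12.4, 7.32, 8.15 and 7.54% for Mki67 or Top2a, 55.2, 24.7, 50.8, 49.6 and 49.2% for Krt15, 41.0, 71.1, 35.5, 37.3 and 40.1% for Krt14, 90.8, 98.1, 93.9, 93.6 and 88.7% for Krt12, and 9.80, 3.82, 10.4, 11.5 and 15.2% for Gpha2. At 2000 UMIs they were 17.2, 26.0, 14.2, 14.9 and 13.8%, then 76.6, 38.5, 71.4, 70.5 and 70.5%, 62.7, 92.0, 54.7, 56.9 and 60.3%, 97.0, 99.7, 98.6, 98.6 and 96.0%, and 21.8, 10.1, 20.6, 20.5 and 30.9%. Without thinning they were 25, 39.8, 20.2, 22.8 and 21.5%, then 89.0, 57.2, 82.3, 81.0 and 85.6%, 79.3, 96.4, 69.6, 73.2 and 76.0%, 99.8, 100.0, 99.8, 99.8 and 99.8%, and 36.8, 23.5, 30.6, 33.4 and 46.1%. At 1000 UMIs, the minimum of 500 UMIs per cell gave 57.0% for Krt15 (day 40), 55.5% for Krt14 (uninjured), and 14.3% (day 5) and 14.5% (day 10) for Gpha2. The minimum of 2000 UMIs gave 58.2% for Krt15 (day 40) and 85.1% for Krt14 (day 2). The 10% mitochondrial limit gave 11.2% (uninjured), 10.2% (day 10) and 9.80% (day 40) for Mki67 or Top2a and 82.7% for Krt14 (day 2). The minimum set per library gave 12.3% (uninjured) and 9.24% (day 40) for Mki67 or Top2a, 58.2% for Krt15 (day 40), 44.5% (day 5) and 49.4% (day 40) for Krt14, 94.0% for Krt12 (uninjured) and 13.8% for Gpha2 (day 10). Keeping called doublets gave 14.6% for Gpha2 (day 10).

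Among list medians (log2), scaling by the median gene ratio gave epithelial proliferation -0.22 (day 5) and -0.018 (day 10) and glycolysis 0.012 (day 10). Taking the mean over cells gave proliferation -0.21 (day 5) and glycolysis 0.022 (day 40). Without the clusters led by proliferation genes, the proliferation median was 1.30 (day 2), -0.46 (day 5) and -0.36 (day 40). The epithelial check for stromal RNA at day 2, at 0.27 in the reported setting, was -1.0 with the minimum of 500 UMIs, -0.50 with the 10% mitochondrial limit, -2.09 at resolution 2 and -0.54 without the top 5% of doublet scores. In stroma, the mitochondrial limit gave corneal differentiation 0.23 (day 2) and conjunctival genes 0.11 (day 2) and 0.19 (day 10), and resolution 2 gave conjunctival genes 0.18 (day 10). Without the top doublet scores, stromal limbal genes were at 0.071 (day 2), wound keratins 0.037 (day 40), EGFR ligands 0.046 (day 5) and the Notch pathway 0.30 (day 10).

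Using uninjured cells of the matching sex turned the most values. For stroma the Y-linked cells also hold less epithelial RNA, so turns of epithelial genes and lists there cannot be assigned to sex. In epithelium the interferon median was -0.95 (day 2), -0.20 (day 5), 2.40 (day 10) and -1.61 (day 40), antigen presentation 0.072 (day 5) and -0.70 (day 40), cornification 0.10 (day 40), wound keratins 0.27 (day 5), wound matrix 0.027 (day 5) and 0.20 (day 40), EGFR ligands 0.059 (day 5), heat shock 0.078 (day 5) and 0.054 (day 40), cytokines 0.28 (day 5), and glycolysis 0.07 (day 5) and 0.12 (day 40). In stroma it gave activated fibroblast genes 0.49 (day 5), niche signals 0.056 (day 2) and 0.24 (day 5), limbal genes 0.23 (day 2) and 0.05 (day 40), corneal differentiation 0.091 (day 5), conjunctival genes 0.10 (day 2) and 0.79 (day 40), wound keratins 0.49 (day 40) and interferon -0.12 (day 5). Single epithelial genes that turned were Cxcl2 2.08 (day 2), Wfdc18 1.81 (day 2) and 2.93 (day 5), Krt17 0.17 (day 40), and, at day 5, B2m -0.57, Ifit1 -0.23, Ifit3 -0.019, Irf7 -0.042 and Isg15 -0.20. Stromal genes that turned, of which all but Krt12 and Krt15 have intervals that include 0 on this baseline of 74 cells, were Akr1b7 0.32, Cmah 1.07, Cxcl12 1.89, Igf1 1.00, Krt12 0.12 and Krt15 0.41 (day 2), Cxcl12 2.40, Iigp1 -0.12, Krt12 0.19, Krt15 2.47, Rspo1 0.14 and Spink5 1.33 (day 5), and Iigp1 -0.27, Krt15 1.5, Krt19 1.00, S100a9 0.25 and Spink5 0.057 (day 40).

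Other settings turned these single genes. Stromal Krt12 at day 2, an epithelial gene, was at 0.11 with the minimum of 2000 UMIs, 0.21 with the mitochondrial limit, 0.12 with doublets kept, 0.10 with the minimum per library and 0.009 without the top doublet scores, and with free RNA subtracted it was 2.23 (day 5), 2.96 (day 10) and 1.49 (day 40). The minimum per library gave stromal Acta2 -0.49 (day 2) and -1.71 (day 10) and Tagln -1.96 (day 2), -0.52 (day 5) and -2.56 (day 10), and the mean over cells gave Tagln -0.26 (day 2). The mitochondrial limit gave stromal Akr1b7 0.60 (day 2) and Krt15 0.12 (day 5), and resolution 2 gave Akr1b7 0.27 (day 2), Krt15 0.34 (day 5) and 0.28 (day 10), and epithelial Mmp3 -0.32 (day 5). Without the top doublet scores, stromal Lcn2 was 0.10 (day 5), Spink5 0.16 (day 10), Mki67 1.02 (day 40) and S100a9 0.26 (day 40). Epithelial Krt19 was 0.68 (day 2) in clusters with Krt12 above Krt13 and Krt4.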

Other observations

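No test was made for this part, and its genes and sub-clusters were singled out after their values had been seen, whereas the lists were fixed beforehand. Gpha2, used as a limbal epithelial marker, was higher in stromal-like than in epithelial-like cells of all 5 libraries, at 515, 1643, 299, 338 and 583 CPM against 256, 75.7, 247, 263 and 359 (uninjured, days 2, 5, 10 and 40), with 203, 137, 188, 192 and 224 in near-empty barcodes. The near-empty values rest on 74, 19, 235, 133 and 31 UMIs. Macrophage-like cells, 37, 465, 187, 90 and 77 of them, had the matrix glycoprotein gene Thbs1 at 65.1, 1523, 320, 282 and 170 CPM and Arg1, an arginine-degrading enzyme of repair macrophages, at 0, 155, 29.2, 50.3 and 15.5, where the 0 and the last value rest on 0 and 3 UMIs. The chemokine Ccl4 was at 7290, 934, 2355, 8041 and 17154 CPM, the cytokine Tnf at 744, 108, 244, 668 and 1568, Cxcl2 at 6732, 3667, 6361, 9925 and 19512, the complement gene C1qa at 3273, 827, 2338, 1924 and 1909, and Apoe at 10768, 5742, 17833, 7588 and 8399. When epithelial-like cells were clustered alone into 18 sub-clusters, sub-cluster 16, led by Sparc and Fscn1, and sub-cluster 17, led by Ecm1 and Krt16 among others, held 26.0 and 26.2% of day 2 epithelium, and 92.1 and 98.0% of their cells came from that library. Sub-cluster 8, led by Ifi27l2a and Ifit3, held 6.93% of day 10 epithelium and drew 80.6% of its cells from it.

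In epithelial-like cells the remaining lists had these median log2 ratios at days 2, 5, 10 and 40: EGFR ligands and growth factors -0.11, -0.15, 0.05 and -0.06, immediate early genes 0.04, -0.06, -0.01 and -0.19, cell cycle inhibitors and senescence 0.18, -0.08, 0.02 and -0.09, the Notch pathway -0.16, -0.10, -0.15 and -0.08, BMP and TGF-beta targets -0.05, -0.45, -0.27 and -0.20, and oxidative phosphorylation 0.16, -0.02, 0.08 and 0.04. Goblet secretion and pluripotency lists had fewer than 3 measured genes and no median in this class; of the pluripotency factors, Klf4 was at 0.40, -0.003, 0.03 and -0.23 and Myc at -0.98, -0.18, -0.002 and -0.08. The stromal check for free RNA was at 0.27, 0.37, -0.10 and 0.30, the check with retinal, lens and blood genes at -0.79, 0.08 and 3.11 at days 2, 5 and 10 with too few genes at day 40, and the sex-linked list at 1.64, 1.88, -4.79 and 1.88. Pro-inflammatory macrophage genes were at -0.55, -0.12, 0.38 and -0.05 and resident or repair macrophage genes at 0.58, 0.49, -0.09 and 0.11 in this class. In stroma they were at 0.95, 0.50, 0.08 and -0.13 and at -0.43, -0.11, -0.59 and 0.62. Other stromal medians were mesenchymal transition 0.37, 0.72, 0.41 and 0.15, heat shock 0.51, 0.43, 0.02 and 0.06, glycolysis 0.54, 0.17, -0.05 and 0.01, cytokines and chemokines 0.43, 0.38, 0.09 and 0.43, the Notch pathway -0.79, -0.91, -0.76 and -0.95, and BMP and TGF-beta targets -0.25, 0.43, 0.26 and 0.41. Against uninjured cells of the matching sex, these epithelial medians changed sign: EGFR ligands and growth factors (0.15, 0.06, -0.03 and 0.28), immediate early genes (-0.10 at day 2 and 0.10 at day 10), cell cycle inhibitors and senescence (-0.001 at day 10), oxidative phosphorylation (0.08 at day 5), and pro-inflammatory (0.99, 0.61 and 1.41 at days 2, 5 and 40) and resident or repair macrophage genes (-0.10 at day 2). Stromal medians that did so were mesenchymal transition (-0.31 and -0.04 at days 2 and 40), heat shock (-0.008 at day 40), glycolysis (-0.12 at day 40), cytokines and chemokines (-0.08 at day 10), and pro-inflammatory (0.57 at day 40) and resident or repair macrophage genes (0.32 at day 5).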
